A study of Mus musculus with 12 samples.

How the data were processed

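RNA of gastrocnemius, a calf muscle, from male mice of 12 weeks on a mixed C57BL6/J and sv129 background was measured on 12 Agilent arrays that read 2 dyes each. PGC-1alpha and PGC-1beta, encoded by Ppargc1a and Ppargc1b, are transcriptional coactivators of mitochondrial and oxidative genes. The mice lacked PGC-1alpha in the whole body, carried a PGC-1beta gene deleted in muscle by a Mlc1f-Cre transgene, or combined both, and the controls carried the floxed PGC-1beta gene without Cre. By their titles, 3 arrays set the alpha knockout, 3 the beta knockout and 3 the double knockout against floxed control RNA, and 3 set the double knockout directly against the alpha knockout. They are called the alpha, beta, double and direct arrays here and are numbered by replicate. The Cy5 dye marked the knockout on the first 9, and the double knockout on the direct arrays, and the Cy3 dye marked the reference; no array had the dyes exchanged.

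The deposited value table gives 1 linear ratio per probe and array, Cy5 over Cy3, made by the authors from background-subtracted signals and multiplied by 1 factor per array. Other details, such as the scanner, the background correction and the scaling, are not given in the sources used here. Ratios of 0 or below stand where a background-subtracted signal was 0 or below, and 1 repeated top value per array, 1e+05 times the factor, stands where the denominator was 0. These values were treated as undefined. The design had taken the table as normalized log ratios; the table was neither on a log scale nor centred, so log2 was taken of the defined ratios. The authors also deposited an up and a down table of mean ratios relative to floxed controls, limited per the labels to a fold of 2 or more and of 0.7 or less. Depth has no meaning for arrays, and their number limits the precision.

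Titles and channel labels named different knockouts on 6 of the 12 arrays. Groups follow the titles. The authors' deposited means of the alpha and double groups equalled those of the arrays grouped by title for 100% of the 9610 down and 5990 up probes found in the value table, within 0.006. Their beta means did so only without the third beta array, again for 100%. Means by the channel labels matched for 0.718% to 2.48% of probes. The third beta array had undefined values at 27.6% of probes, and its log2 ratios correlated at -0.44 with those of the first beta array, although both carry the same condition in their titles. Other correlations below -0.3 among the 9 arrays against floxed RNA were those of the third beta array with alpha 1 (-0.44) and double 1 (-0.39), and those of double 3 with alpha 1 (-0.33) and beta 1 (-0.31). Directions were kept as the dyes state them. No pair among the 66 was identical.

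Of 40928 probes, 32443 carried 1 gene symbol, 44 several and 8441 none; the probes with 1 symbol stood for 19437 genes. Log2 ratios were averaged over the probes of a gene. A gene entered a fit with a value on at least 2 arrays of every group. In the planned fit, called the 12-array fit, limma 3.58.1 in R 4.3.3 gave each of the 4 title groups a mean and all groups 1 shared spread, with lmFit, eBayes and Benjamini-Hochberg adjustment over all genes tested at 0.05. Groups against floxed RNA were tested against a log2 ratio of 0. The double minus the beta group tested the double against the beta knockout, and the double minus the alpha minus the beta group tested for a non-additive response. All tests were two-sided. The ratio against 0 leaves out the spread between control samples, since the labels do not say whether 1 or several control mice supplied the RNA. For the same reason p-values measure the spread between arrays, which are not known to be separate mice.

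An added fit, the 11-array fit, was chosen after seeing the data. It left out the third beta array and centred each array on its median gene. Ratios on fractions of whole numbers up to 10 times the array factor, which dim or equal signals give, were left out too. This rule for dim or equal signals reads the ratio and not the signal. It can therefore also leave out a brighter signal whose ratio falls on such a fraction. The 11-array fit tested 11175 genes, against 16984 in the 12-array fit. Log2 ratios printed for genes and lists come from the 11-array fit unless the 12-array fit is named. Before centring, the array medians of log2 ranged from -1.49 on direct 3 to 0.20 on double 3, so every ratio is relative to the median gene of its array.

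Both fits were tested on simulated data, with 100 genes shifted at each of 2 sizes. The data were random normal values with the missing values and the residual spread of each array. That spread was the same for every gene, and the values were not correlated between genes or arrays. Recovery and false calls in the real data may therefore differ. At a log2 of 2 the 12-array fit recovered 1% to 45% of them, with 119 false calls among 170 on the beta arrays. The 11-array fit recovered 97% to 100% at a log2 of 2 and 22% to 45% at a log2 of 1. Its false calls were 1 of 130 on the alpha, 2 of 121 on the beta, 20 of 161 on the double and 9 of 153 on the direct arrays, so the share on the double and the direct arrays was above the nominal 5%.

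Shifts of 30 gene lists fixed before the data were examined were tested with limma's camera on the moderated statistics with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The lists cover the respiratory chain and its partner pathways, contractile genes of slow and fast fibres, and stress, clock and lipid genes. They also cover markers of other cell types in muscle. Of their 563 genes 516 matched a probe, and a list needed 3 measured genes. Among the matches, Gpi1 of the glycolysis list was taken by its symbol as Pigq, which is a different gene. Named genes followed a rule fixed at the same time. It took Ppargc1a and Ppargc1b, up to 3 genes per list with the largest change past the threshold and the same sign on every array (the 2 with the smallest p where a shifted list had none), and the 5 highest and 5 lowest outside the lists. The text names a part of these, and each gene named outside the rule is said to be so. Random lists and splits used fixed seeds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

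Alternatives planned beforehand were centring and scaling of arrays, tests at probe level, complete genes only, groups by channel labels, replicate number as a fixed or random block, a dye term, only the arrays of a comparison, the authors' fold limits, leaving out each replicate number, and other set tests. The labels do not say that a number pairs arrays across groups. Alternatives added after seeing the data were leaving out the third beta array, array weights, and, for the 11-array fit, keeping the third beta array, keeping dim signals, no centring, centring within classes of probe dimness and leaving out each further array.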

Results

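The series holds 12 arrays of mouse gastrocnemius in 4 groups of 3, and 1 array of the beta group was left out of the 11-array fit, which leaves 2. Between 47.8% and 74.2% of the 40928 probes gave a defined ratio that the rule for dim or equal signals did not leave out. Undefined ratios made up 27.6% on beta 3, 23.7% on direct 3, 21.5% on double 3 and 8.39% to 15.1% on the other 9 arrays. The median log2 of bright minus dim probes was 0.89 to 2.35 on the alpha arrays, beta 1, beta 2 and double 1, -0.06 on double 2, and -4.80, -2.44, -1.10, -0.83 and -3.38 on beta 3, double 3 and direct 1 to 3, so that this trend ran opposite ways on the alpha and the direct arrays.

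The expression of the targeted genes was compared first. Ppargc1a, on chromosome 5 (51454249 to 52115853, GRCm38.p6), had a log2 ratio of -1.47 ± 1.04 (SD, n = 3) on the alpha arrays, which passed limma's test (adjusted p = 0.0202). On the double arrays it was -1.34 ± 0.55 (SD, n = 3), with an adjusted p of 0.0784, and on the beta arrays it was -0.29 ± 0.29 (SD, n = 2), with an adjusted p of 0.771. Ppargc1b, on chromosome 18 (61291445 to 61400756), was not lower on beta 1 and beta 2, titled as its own knockout, at 0.75 ± 0.20 (SD, n = 2; adjusted p = 0.348). It rose on the alpha arrays to 1.12 ± 0.36 (SD, n = 3; adjusted p = 0.0327) and was 0.27 ± 0.09 (SD, n = 3; adjusted p = 0.691) on the double arrays. On the direct arrays Ppargc1b fell by 1.16 on the log2 scale (SD 0.90, n = 3; adjusted p = 0.0298), and Ppargc1a was at 0.75 ± 0.20 (SD, n = 3; adjusted p = 0.165). Probes of 1 gene disagreed, relative to the median probe of an array. The 2 of Ppargc1a averaged -2.61 (SD 0.93, n = 2) and -1.02 (SD 0.77, n = 3) on the alpha, -0.91 and 0.35 (SD 0.17 and 0.45, n = 2) on the beta and 1.47 and -0.02 (SD 0.27 and 0.41, n = 3) on the direct arrays. The 3 of Ppargc1b averaged 1.61, 1.93 and -0.17 (SD 0.19, 0.63 and 0.62, n = 3) on the alpha and -1.12, -2.11 and -0.34 (SD 0.61, 1.19 and 1.08, n = 3) on the direct arrays. Whether the probes of either gene lie in the deleted part is not known here, so the genotypes rest on the titles. None of these ratios passed the threshold in the 12-array fit. Keeping beta 3, where Ppargc1b was at -0.67 and Ppargc1a at -0.88, and changing nothing else gave 0.28 and -0.48 on the beta arrays, and the 12-array fit, which also keeps dim signals and is not centred, gave 0.02 and -0.85. On the direct arrays it gave -1.79 for Ppargc1b and 0.12 for Ppargc1a.

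**Figure D1:**
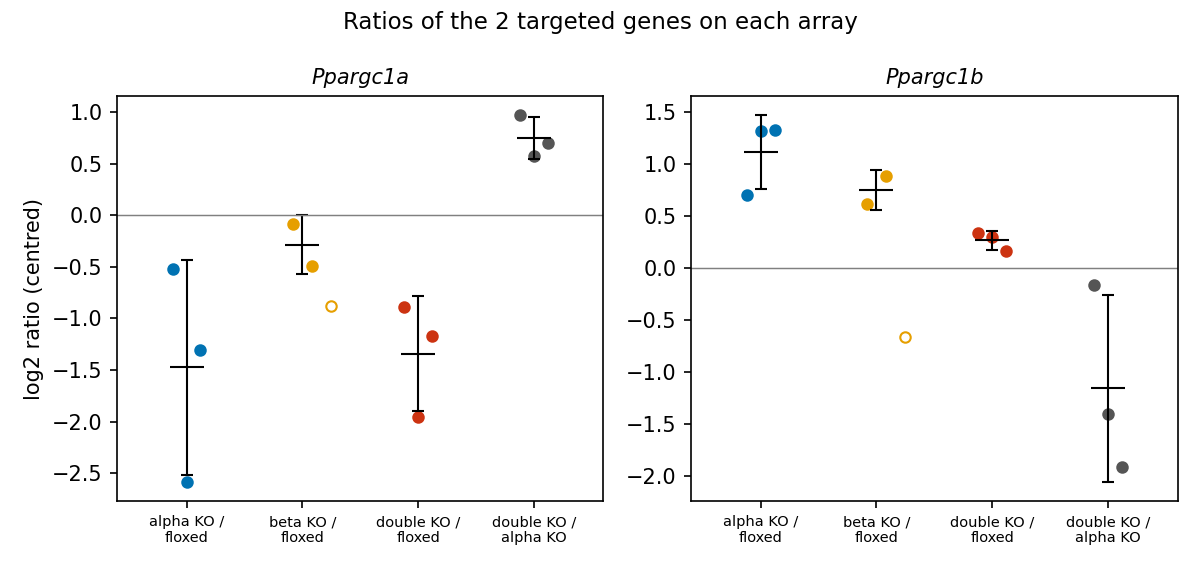
Log2 ratio of Ppargc1a and Ppargc1b (y axis, relative to the array's median gene) on each array of the 4 groups (x axis; KO, knockout); filled points are arrays of the 11-array fit, the open point is beta 3, and bars are the mean and SD of the filled points. Ppargc1a averages -1.47 on the alpha and -1.34 on the double arrays, and Ppargc1b lies above 0 on every alpha, double and filled beta point.

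The double knockout against floxed controls addresses which genes change in muscle without both coactivators, with the genotype as titled, since Ppargc1b was not lower. Genes of the respiratory chain were lower on the double arrays in each complex. Of the measured genes, 8 of 33 in complex I, 7 of 12 in complexes II and III, 5 of 14 in complex IV and 5 of 13 of ATP synthase fell, and 0 rose. Adjusted over the list alone, 16, 10, 7 and 10 fell. Among them were Cycs, which encodes the electron carrier cytochrome c, at -2.38 ± 0.32 (SD, n = 3; adjusted p = 0.00341), the cytochrome c oxidase subunits Cox7c at -2.30 ± 0.13 and Cox5b at -2.04 ± 0.20, and the Rieske iron-sulfur protein Uqcrfs1 at -1.99 ± 0.22 (each SD, n = 3). Ndufv1, a complex I subunit that binds NADH, was at -1.77 ± 0.08 (SD, n = 2), the ATP synthase subunit Atp5k at -1.88 ± 0.45 and the succinate dehydrogenase subunit Sdhb at -2.16 ± 1.11 (each SD, n = 3). For Ndufv1 the deposited ratio of 0.402 on double 1 was left out by the rule for dim or equal signals.

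Some fuel-oxidizing genes fell with them on the double arrays. Of the citric acid cycle list 3 of 19 genes fell, of fatty acid oxidation 3 of 20 and of mitochondrial import and dynamics 1 of 26, and 0 rose; adjusted over the list alone these were 12, 8 and 1. Dlat, a subunit of the pyruvate dehydrogenase complex, was at -1.44 ± 0.28, the fumarase gene Fh1 at -1.40 ± 0.26 and Acadl, which starts the oxidation of long acyl chains, at -1.75 ± 0.78 (each SD, n = 3). The mitochondrial phosphate carrier Slc25a3 was at -1.59 ± 0.53 (SD, n = 3). In the antioxidant list 2 of 16 genes fell, the mitochondrial Txn2 (-1.60) and Sod2 (-1.46), and 1 rose, the transhydrogenase Nnt (1.19); adjusted over the list alone 3 rose and 3 fell. The triglyceride lipase Pnpla2 (-1.63), the growth factor Vegfb (-1.22) and the collagen chain Col6a1 (-1.87) fell.

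Contractile genes of slow fibres rose on the double arrays, 4 of 13 genes past the threshold and 9 adjusted over the list alone, with 0 lower. Tnnt1, slow troponin T, was at 2.24 ± 0.88, the slow myosin Myh7 at 1.74 ± 0.41 and slow troponin C, Tnnc1, at 1.59 ± 0.70 (each SD, n = 3). Tnnt1 was also at 2.22 on the alpha arrays and at 1.88 on beta 1 and beta 2 (-3.03 on beta 3). The median of the slow-fibre list was also much alike on the double arrays, the alpha arrays, and beta 1 and beta 2, which all hold floxed RNA. In the 11-array fit camera did not shift the list on the direct arrays or in double minus beta. A source in the floxed control RNA was therefore not excluded for Tnnt1 or for the list. Myh7 was at 0.94 on the alpha arrays, 0.72 on beta 1 and beta 2, and 1.32 on the direct arrays, which hold no floxed RNA. Of the 12 fast-fibre genes 0 passed (1 adjusted over the list alone), with 11 above 0, among them Actn3, the fast alpha-actinin, at 1.02 (adjusted p = 0.0705) and Myoz1 at 0.59 (adjusted p = 0.147). Outside the lists Chchd10, on chromosome 10 (75933130 to 75937750), which encodes a protein between the mitochondrial membranes, was at -3.08 ± 0.27 (SD, n = 3; adjusted p = 0.000172), which is 8.45-fold lower. Hsbp1l1 (-3.30), the GTPase Rab6b (-3.13), Tmc7 (-3.00) and Fuom (-2.93) fell, and Insig1, which restrains sterol synthesis (3.81 ± 1.38, SD, n = 2), Itsn1 (3.58), Pcyt1b (3.35), Ocel1 (2.61) and Kcne1l (2.57) rose. Nrf1, a transcription factor of respiratory genes, rose to 1.28 ± 0.14 (SD, n = 2). Insig1, Itsn1, Pcyt1b and Nrf1 were at 1.22, 0.48, 0.91 and 0.43 on the double arrays in the 12-array fit, each with an adjusted p of 0.9998.

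In all, 194 of 11175 genes changed on the double arrays, 66 higher and 128 lower, against 0 in limma's 12-array fit (747 at an unadjusted p under 0.05). With camera, lists shifted down were complex I (median -0.80, adjusted p = 9.09e-14), complexes II and III (-1.25, 1.54e-11), complex IV (-0.63, 5.59e-09), ATP synthase (-1.03, 3.51e-10), the citric acid cycle (-0.90, 9.94e-10), fatty acid oxidation (-0.54, 1.22e-06) and import and dynamics (-0.42, 0.00221). Slow-fibre (1.03, 1.00e-10) and fast-fibre genes (0.43, 0.00191) shifted up. With an estimated correlation 7 of the 9 held; the adjusted p was 0.0828 for the citric acid cycle and 0.482 for import and dynamics with an estimated correlation. The other 21 lists had adjusted p of 0.0508 or more, with medians of -0.34 to 0.27. Among them, marker lists of other cells had medians of -0.29 (endothelial), -0.0028 (macrophage and leukocyte), 0.14 (fibroblast and matrix), -0.26 (adipocyte), -0.33 (Schwann cell and nerve) and 0.20 (red blood cell). The count fell to 17 with beta 3 kept (132 with array weights on 12 centred arrays), 1 with a dye term, 34 without centring, 72 with dim signals kept, and 0 by channel labels or with the double arrays alone. It was 100, 110 and 80 without alpha 1, alpha 2 or alpha 3, 107 without either beta array, 86, 49 and 66 without double 1, double 2 or double 3, and 119 without direct 2.

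**Figure D2:**
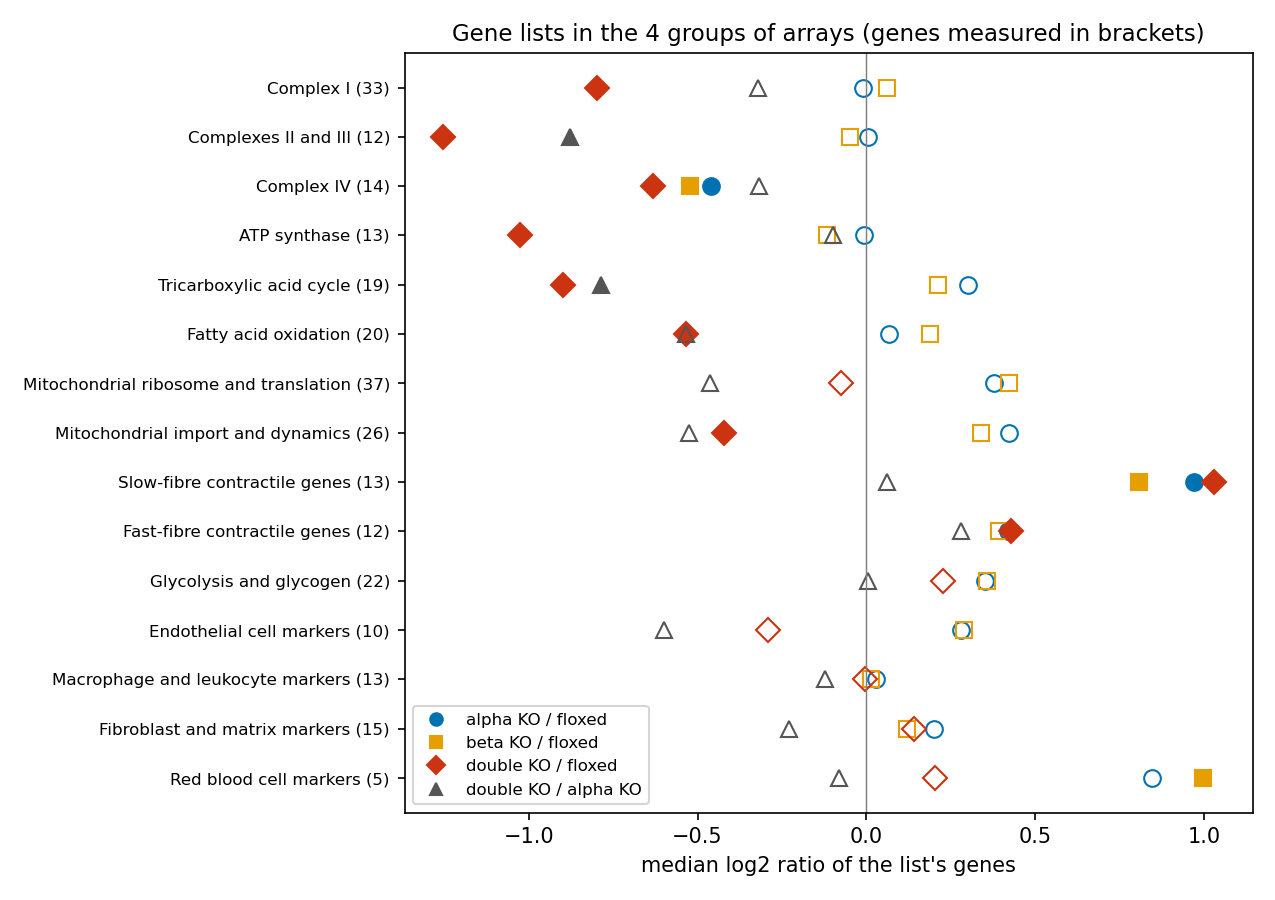
Median log2 ratio (x axis) of the genes of 15 lists (y axis, with the number measured) in the 4 groups of arrays, 11-array fit; filled symbols mark an adjusted p under 0.05 in camera with its preset correlation. The respiratory chain lists lie between -1.25 and -0.63 on the double arrays, and slow-fibre genes lie at 0.81 to 1.03 on all 3 groups against floxed RNA.

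**Figure D3:**
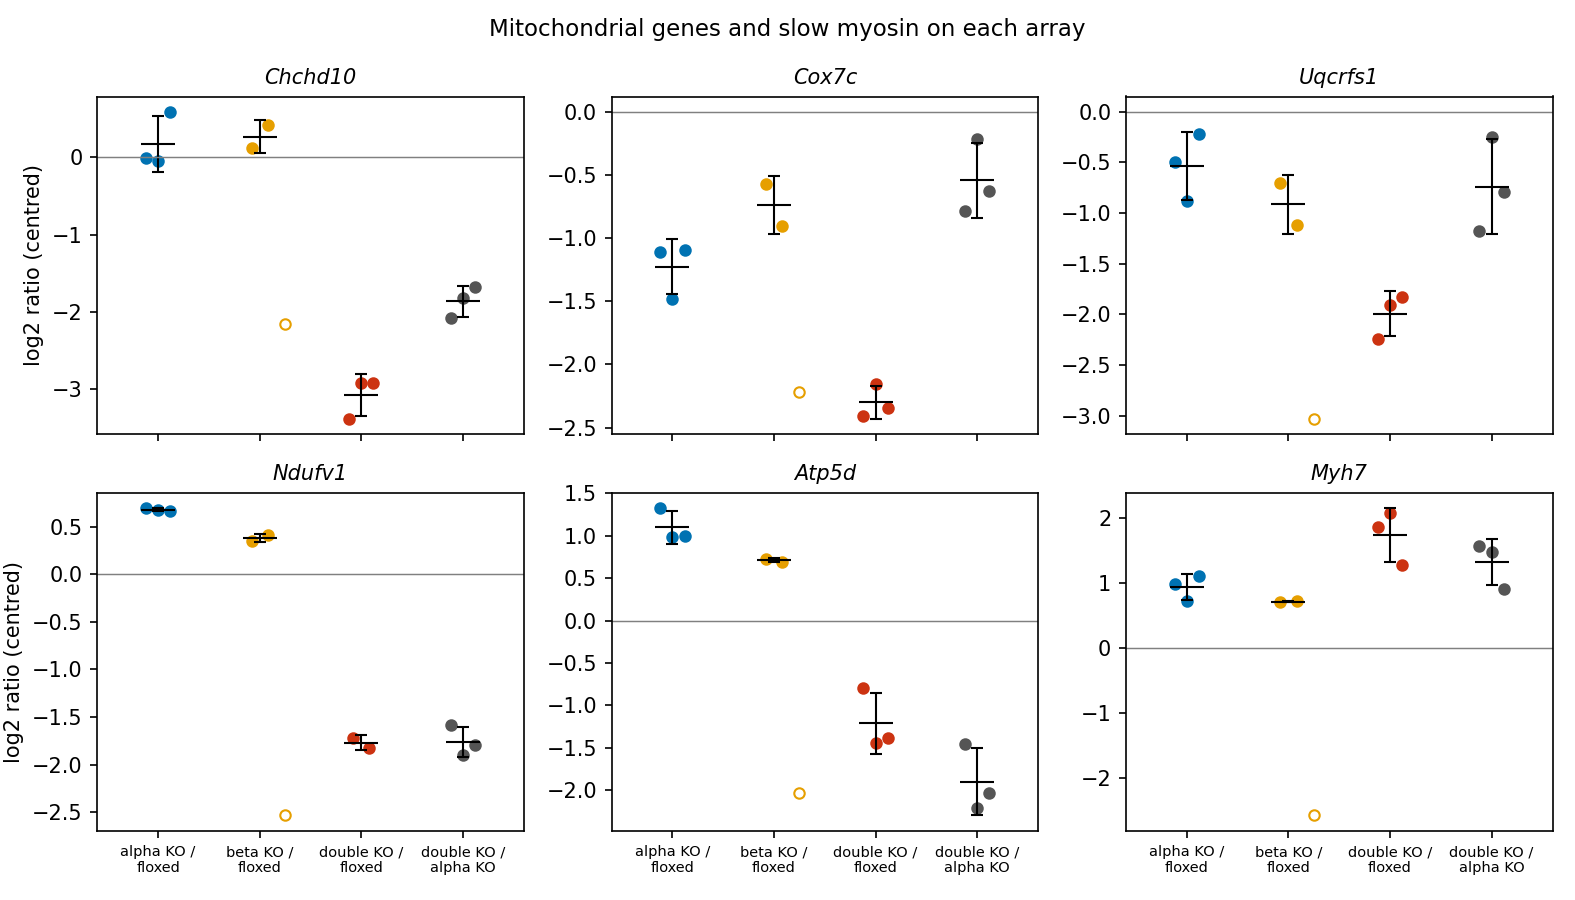
Log2 ratio (y axis, relative to the array's median gene) of 6 genes on each array of the 4 groups (x axis; KO, knockout); filled points are arrays of the 11-array fit, open points beta 3, and bars the mean and SD of the filled points. Chchd10 averages -3.08 on the double and -1.86 on the direct arrays, against 0.18 on the alpha arrays and 0.27 on beta 1 and beta 2, with beta 3 at -2.16.

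The alpha knockout against floxed controls addresses the loss of PGC-1alpha alone. The histone demethylase Kdm6b rose to 3.73 ± 0.12 (SD, n = 2; adjusted p = 0.00251), the calcium channel subunit Cacna2d1 to 2.62 ± 0.13 and Fez1 to 2.56 ± 0.65 (each SD, n = 3). Bckdk, the kinase that restrains breakdown of branched-chain amino acids, rose to 2.50 ± 0.48, the catalytic AMP kinase subunit Prkaa2 to 2.03 ± 0.39 and the peroxidase Prdx2 to 1.97 ± 0.27 (each SD, n = 3). Clec3b (2.41), Ier3 (1.95), the mitophagy receptor Bnip3 (1.90), Ddit4 (1.75), hexokinase 2 (Hk2, 1.43) and the lipid phosphatase Lpin1 (1.43) rose. Ugt2b34 (-3.81), Tlx1 (-3.62), Rpgrip1 (-3.45), BC048679 (-3.33) and 1700066C05Rik (-3.30) fell. Before centring, probes dim on 9 or more arrays had median log2 ratios of -1.63, -1.04 and -0.97 on alpha 1 to 3. On direct 1 to 3 their medians were 1.02, 0.88 and 1.13, and 1700066C05Rik averaged 1.86 there. The signals of the genes that fell are not given here, so a share of this trend in their fall stays open.

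Slow-fibre genes rose on the alpha arrays, 8 of 13 (10 adjusted over the list alone), with 0 lower. As on the double arrays, a source in the floxed control RNA was not excluded for this list. Tnnt1 was at 2.22 ± 0.11, Ankrd2 at 1.31 ± 0.32 and the slow tropomyosin Tpm3 at 1.25 ± 0.33 (each SD, n = 3), and of the fast-fibre list 3 of 12 rose (3 adjusted over the list alone, with 1 lower), with Actn3 at 1.89 ± 0.49 (SD, n = 3). Of complex IV 3 of 14 genes fell and 1 rose (4 and 1 adjusted over the list alone). Cox7b was at -1.80 ± 0.15 (SD, n = 2) and Cox7c at -1.23 ± 0.22 (SD, n = 3), while Surf1, an assembly factor of the complex, was at 1.30 ± 0.56 (SD, n = 3). Members of the other mitochondrial lists went both ways. Ndufa10 of complex I (1.75), Sdhc of succinate dehydrogenase (1.55), Mrpl2 of the mitochondrial ribosome (1.54), the aspartate transaminase Got2 (1.22) and Atp5g1 (1.17) rose, and the import subunit Tomm7 (-1.84) and the thioesterase Acot13 (-1.29) fell. Nrip1, a corepressor of oxidative genes, rose to 1.35 ± 0.52 (SD, n = 3).

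On the alpha arrays 1499 genes changed, 1050 higher and 449 lower. The 12-array fit called 4 genes, all lower and none with a value in the 11-array fit: Mrgpra2b (-4.30), Orly (-4.89), Pole2 (-3.55) and Serinc4 (-4.72), chosen as its whole set. Camera shifted slow-fibre genes up (median 0.97, adjusted p = 7.31e-05) and complex IV down (-0.46, 0.00805), and the adjusted p was 0.424 for both with an estimated correlation. The red blood cell list had a median of 0.84 (adjusted p = 0.164), with the hemoglobin gene Hba-a2 at 1.53 ± 0.59 (SD, n = 3; adjusted p = 0.00919). The count was 84 with beta 3 kept, 123 without centring, 409 with a dye term, 660 with the alpha arrays alone and 4893 with array weights on 12 centred arrays. It was 243, 460 and 66 without alpha 1, alpha 2 or alpha 3.

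On beta 1 and beta 2, titled as beta knockout against floxed controls, where Ppargc1b was not lower (-0.67 on beta 3, and 0.28 with it kept), 1 gene changed. Tnfrsf12a, a receptor of the tumour necrosis factor family on chromosome 17 (23675445 to 23677449), rose to 2.13 ± 0.34 (SD, n = 2; adjusted p = 0.0357). Slow-fibre genes were above 0 in 12 of 13 cases, with Tnnt1 at 1.88 ± 0.14 and Ankrd2 at 1.49 ± 0.65 (each SD, n = 2; both adjusted p = 0.108). With beta 3 kept and nothing else changed, Tnnt1 was at 0.24, Ankrd2 at 0.30, Cox7c at -1.23, Hba-a2 at 0.99 and Hbb-bt at 0.69, and in the 12-array fit they were at -0.13, -0.07, -1.60, 0.61 and 0.32. Over all genes 0 of the list passed, and 8 rose adjusted over the list alone. Complex IV genes were below 0 in 12 of 14 cases, with Cox7b at -1.57 ± 0.07 and Cox7c at -0.74 ± 0.23 (each SD, n = 2; adjusted p = 0.142 and 0.209); 0 passed over all genes and 1 fell adjusted over the list alone. Of the 5 red blood cell genes 4 rose adjusted over the list alone and 0 over all genes, with Hba-a2 at 1.60 ± 0.41 and Hbb-bt at 1.36 ± 0.22 (each SD, n = 2).

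Camera shifted slow-fibre genes up on the beta arrays (median 0.81, adjusted p = 1.51e-05), complex IV down (-0.52, 0.00654) and red blood cell genes up (1.00, 0.0115). With an estimated correlation none held, and the adjusted p was 0.302, 0.317 and 0.302 with an estimated correlation. In the 12-array fit 0 lists shifted up and 5 down, complexes I (median -1.25), II and III (-1.25) and IV (-1.46), ATP synthase (-1.18) and import and dynamics (-1.02), and slow-fibre genes had a median of -0.16; 0 of the 5 held with an estimated correlation. At an unadjusted p under 0.05 limma gave 1754 genes, and the 12-array fit gave 0 at the adjusted threshold and 1630 at the unadjusted. The count was 0 with dim signals kept, without centring, with a dye term or with the beta arrays alone, 2 by channel labels, 0 with beta 3 kept and 1022 (484 higher, 538 lower) with array weights on 12 centred arrays. It was 3 without beta 1 and 0 without beta 2, any alpha array or any direct array.

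The direct arrays, titled double against alpha knockout, hold no floxed RNA and address what the loss of PGC-1beta adds. Some oxidative genes were lower on them. Sdhb fell to -2.36 ± 0.71, Sdhc to -1.87 ± 0.24 and Cyc1, cytochrome c1, to -1.87 ± 0.28 (each SD, n = 3), and 6 of 12 genes of complexes II and III fell with 0 higher (7 adjusted over the list alone). Of the citric acid cycle list 5 of 19 fell and 0 rose (7 adjusted over the list alone), among them the transaminases Got2 (-1.84) and Got1 (-1.64) and Dld (-1.63). In the mitochondrial ribosome list 11 of 37 fell and 2 rose (12 and 2 adjusted over the list alone), with Mrpl46 at -2.41 ± 1.83 (SD, n = 3). In complex I 6 of 33 fell and 1 rose (9 and 6 adjusted over the list alone), with Ndufa10 at -2.11 ± 0.81 (SD, n = 2). In complex IV 2 of 14 fell and 1 rose (3 and 1 adjusted over the list alone), Cox7b at 1.30 ± 0.78 (SD, n = 3; adjusted p = 0.0258).

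Several genes that rose on the alpha arrays were lower on the direct arrays, where alpha knockout RNA is the denominator. Kdm6b fell to -3.17 ± 0.43, Prkaa2 to -2.36 ± 0.75, Prdx2 to -2.11 ± 0.95, the stress transcription factor Atf4 to -1.70 ± 0.18 and the matrix gene Fmod to -1.91 ± 0.91 (each SD, n = 3). Gabpa, a transcription factor of respiratory genes, fell to -1.60 ± 1.02 (SD, n = 3), as did Atp5d (-1.90), Echs1 (-1.34), the endothelial Cldn5 (-1.92), Cdh5 (-1.20) and Esam (-0.75), 3 of 10 genes of that list with 0 higher (4 adjusted over the list alone), Vegfb (-1.06), Scand1 (-2.79), Helb (-2.66), Rbm12b1 (-2.65) and Tor1b (-2.58). Aldolase A (Aldoa, 2.40 ± 0.29, SD, n = 2), the calcium buffer of fast fibres Pvalb (2.03 ± 0.54, SD, n = 2), Myh7 (1.32 ± 0.36, SD, n = 3), the mitochondrial chaperone Hspe1 (1.59) and embryonic myosin Myh3 (1.52) rose. Efcab3 (3.44), Kcne1l (2.60) and the glutamate transporter Slc1a3 (2.57) rose outside the lists. In the 12-array fit, which is not centred and has its median gene at -0.53 on the direct arrays (-0.13 in the 11-array fit), Aldoa was at 1.56, Pvalb at 1.31, Myh7 at 0.70, Hspe1 at 0.97, Myh3 at 0.89, Efcab3 at 1.72 and Cox7b at 0.67, and Vegfb at -1.69, Cdh5 at -1.83 and Esam at -1.38, none past the threshold.

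In total 1418 genes changed on the direct arrays, 461 higher and 957 lower, against 0 in limma's 12-array fit (3107 at an unadjusted p under 0.05). Camera shifted the citric acid cycle (median -0.79, adjusted p = 0.00980) and complexes II and III (-0.88, 0.0216) down, and the adjusted p was 0.626 and 0.279 with an estimated correlation. Across 11175 genes, which are not independent replicates, the direct ratio, from the same kinds of RNA on other arrays, correlated with the double minus the alpha ratio at a Pearson r of 0.605 and a Spearman rho of 0.623, and 74.0% of all genes and 94.9% of the 1418 had the same sign in both. Over the 20 splits of the 6 alpha and double arrays, direction included, the Pearson r was -0.605 to 0.605, highest with the real split and 0.474 at most with another, a share of 1 in 20 that is the smallest they can give. Centred within classes of dimness the real r was 0.601. The test of direct against double minus alpha called 0 genes in limma (435 at an unadjusted p under 0.05). The count was 172 with beta 3 kept, 761 by channel labels and 0 with the direct arrays alone. It was 343 and 310 without direct 2 or direct 3. With the dye term the test becomes double minus alpha, which uses no direct array. That test called 8 genes, and Efcab3 turned to -0.36 in it.

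The double against the beta knockout was compared through the floxed reference, so that the dye cancels. The control cancels too only if the arrays held the same control RNA, which the labels do not say. Chchd10 was the 1 gene that changed, at -3.35 ± 0.34 (SE; adjusted p = 0.00856), which is 10.2-fold lower. With beta 3 kept, where it was at -2.16, the difference was -2.54 (adjusted p = 0.752), and -2.21 (0.999) in the 12-array fit. Oxidative genes were lower as lists in the 11-array fit. The 20 measured fatty acid oxidation genes were all below 0, as were 11 of 12 in complexes II and III, 12 of 13 of ATP synthase, 18 of 19 of the citric acid cycle and 28 of 33 in complex I. Examples that did not pass on their own were Ndufv1 at -2.15 (adjusted p = 0.105), Atp5d at -1.92 (0.147), Sdhc at -1.99 and Uqcrc1 at -1.56 (both 0.170), Cox7c at -1.56 (0.224) and the acyl-CoA dehydrogenase Acadvl at -1.43 (0.319). These were at -0.66, -0.68, -1.18, -0.54, -0.74 and 0.31 in the 12-array fit, in the same order.

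Camera shifted 12 of 30 lists down between double and beta. These were complexes II and III (median -1.10, adjusted p = 1.73e-09), ATP synthase (-0.70, 1.87e-06), fatty acid oxidation (-0.89, 6.46e-07) and lipid synthesis and storage (-0.75, 0.00287), which held with an estimated correlation, at adjusted p = 6.98e-05, 0.00292, 0.0348 and 0.00330. Complex I (-0.81, 2.54e-09), complex IV (-0.57, 0.00287), the citric acid cycle (-1.11, 1.73e-09), the mitochondrial ribosome (-0.46, 0.00201) and import and dynamics (-0.81, 4.14e-05) did not hold, at adjusted p = 0.125, 0.246, 0.125, 0.367 and 0.347 with an estimated correlation. Nor did mitochondrial DNA maintenance (-0.48, 0.0433), the circadian clock (-0.48, 0.0495) or red blood cell genes (-0.83, 0.0307), at adjusted p = 0.505, 0.483 and 0.342 with an estimated correlation. In the 12-array fit, which keeps beta 3, camera shifted 0 lists down and 2 up, slow-fibre (median 1.28) and fast-fibre genes (0.86, both adjusted p = 0.0346), and neither held with an estimated correlation. Adjusted over the list alone, 9 genes of complex I, 8 of complexes II and III, 5 each of ATP synthase and the citric acid cycle, 4 of fatty acid oxidation and 3 of complex IV fell, and 0 over all genes. Limma gave 888 genes at an unadjusted p under 0.05, and 0 at the adjusted threshold in the 12-array fit (498 unadjusted). The count was 27 with array weights on 12 centred arrays, and 0 with beta 3 kept, without centring, with centring by dimness class, by channel labels, with the arrays of the comparison alone and without either beta array, 3 with complete genes only, and 2 without double 1.

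The non-additive response compares the double ratio with the sum of the alpha and beta ratios. Below the sum were Sdhb (-3.82 ± 0.79), Sdhc (-3.54 ± 0.45), Ndufv1 (-2.83 ± 0.38), Atp5g1 (-3.12 ± 0.51), Atp5d (-3.02 ± 0.42), Got2 (-3.15 ± 0.55) and Got1 (-3.07 ± 0.59), each with its SE and past the threshold. So were Prkaa2 (-3.54 ± 0.65), Prdx2 (-3.53 ± 0.65), Bnip3 (-2.82 ± 0.57), Atf4 (-2.45 ± 0.39), Kdm6b (-3.98 ± 0.64) and Mpv17l2, a mitochondrial membrane protein (-4.20 ± 0.57, each SE). Above the sum were Tomm7 (2.85 ± 0.57), Myh3 (2.48 ± 0.49), Ugt2b34 (5.39 ± 1.00) and the glutamate receptor Grid1 (5.16 ± 0.77, each SE). Ugt2b34 was at -3.81 on the alpha arrays, where dim probes were low as well, and its signal is not given here. Ndufv1 was at -1.40 in the 12-array fit, Atp5g1 at -1.76, Atp5d at -1.84, Got1 at -1.90, Bnip3 at -1.52, Kdm6b at -2.19 and Grid1 at 1.64, and 0 genes passed there. Of complexes II and III 4 of 12 genes were below and 0 above (6 and 0 adjusted over the list alone), of ATP synthase 5 of 13 (5 adjusted over the list alone), of complex I 4 of 33 (10) and of lipid synthesis and storage 2 of 16 (6).

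In all, 401 genes departed from the sum, 98 above and 303 below, against 0 in limma's 12-array fit (1160 at an unadjusted p under 0.05). Camera shifted 9 lists down, of which complexes II and III (median -1.46, adjusted p = 0.000538) and lipid synthesis and storage (-0.94, 0.00788) held with an estimated correlation, at adjusted p = 0.0414 and 0.0140. The others were complex I (-0.89, 0.00788), ATP synthase (-0.57, 0.0314), the citric acid cycle (-1.36, 0.000538), fatty acid oxidation (-1.14, 0.0168), the mitochondrial ribosome (-0.90, 0.0103), import and dynamics (-1.06, 0.00415) and red blood cell genes (-1.53, 0.0190). For these the adjusted p was 0.453 or 0.465 with an estimated correlation. The sum counts the control RNA and the dye once more than the double ratio does. The direct minus the beta ratio, which frees the comparison of the dye but holds the control once, called 1521 genes, 504 higher and 1017 lower, but 0 lists with camera (8 at an unadjusted p under 0.05), with a median of -0.17 for complex I and 0.33 for ATP synthase. With the dye term the non-additive test becomes the direct minus the beta ratio, so its 1521 genes are the same result. The count of 401 became 1959 with array weights on 12 centred arrays and 204 with dim signals kept. It became 0 with beta 3 kept, without centring, by channel labels, or without alpha 3, beta 1 or beta 2. It was 94, 78, 73 and 54 without alpha 1, alpha 2, double 2 or double 3, 888 and 638 without double 1 or direct 3, and 260 without direct 2.

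**Figure D4:**
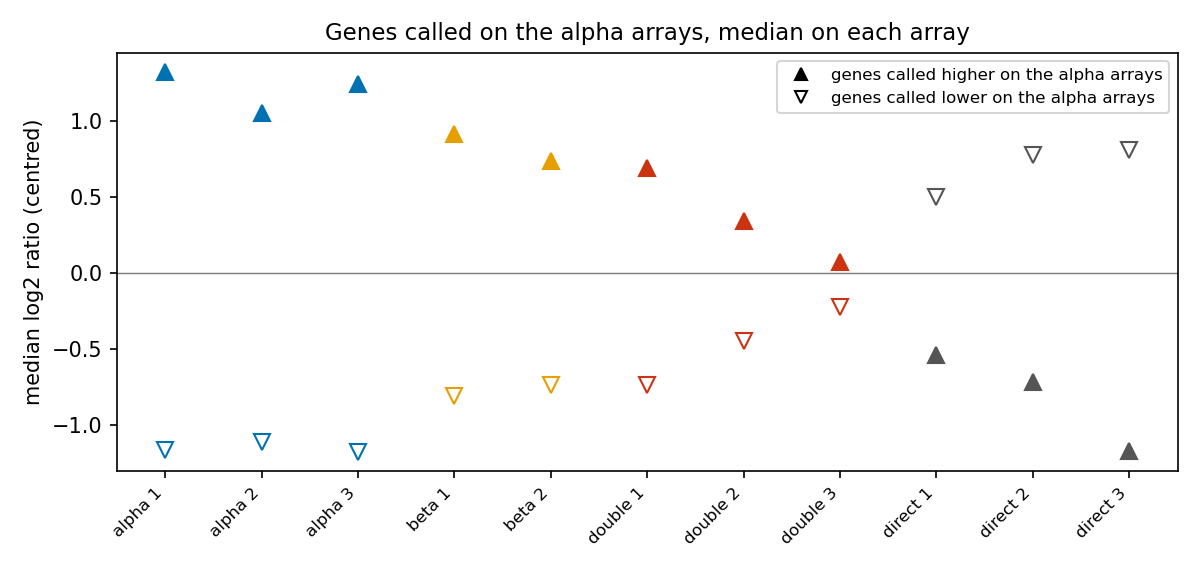
Median log2 ratio (y axis, relative to the array's median gene) of the 1050 genes called higher (filled) and the 449 called lower (open) on the alpha arrays, for each of the 11 arrays (x axis). The genes called higher have medians of 0.74 and 0.91 on the beta arrays and of -1.17 to -0.54 on the direct arrays.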

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

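The tests weighed here were all chosen after the results were seen, and the 11-array fit was too. What brought these results forward is a difference between groups, the ratio on the arrays titled as double knockout against the sum of the ratios on those titled as single knockouts, by a test of the difference itself. The non-additive count of 401 genes and the count of 1521 genes that differed between the direct and the beta arrays are of this kind. Lists below the sum had medians of -0.89 (complex I), -1.46 (complexes II and III), -0.57 (ATP synthase), -1.36 (citric acid cycle), -1.14 (fatty acid oxidation), -0.90 (mitochondrial ribosome), -1.06 (import and dynamics), -0.94 (lipid synthesis and storage) and -1.53 (red blood cell markers). Of these 9 only complexes II and III and lipid synthesis and storage held with an estimated correlation (adjusted p = 0.0414 and 0.0140; 0.453 or 0.465 for the other 7), and the direct minus the beta ratio called 0 lists with camera (8 at an unadjusted p under 0.05).

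Genes of the respiratory chain below the sum, with log2 differences, were Ndufa10 (-3.84), Ndufv1 (-2.83), Ndufa9 (-1.79), Sdhb (-3.82), Sdhc (-3.54), Cyc1 (-2.77), Atp5g1 (-3.12), Atp5d (-3.02) and Atp5g2 (-2.34). Genes of fuel oxidation below it were Got2 (-3.15), Got1 (-3.07), Idh3a (-2.80), Echs1 (-2.31), Decr1 (-2.24) and Slc25a20 (-1.78), and the ribosomal Mrpl2 was at -2.58. Prdx2 (-3.53), Prkaa2 (-3.54), Actn3 (-2.26), Bnip3 (-2.82), Atf4 (-2.45), Bhlhe40 (-1.79), Lpin1 (-2.22), Acacb (-1.65), Fmod (-2.66) and Hba-a2 (-2.37) were below the sum too. Outside the lists Zfp445 (-4.32), Mpv17l2 (-4.20) and Kdm6b (-3.98) were below it. Tomm7 (2.85), Myh3 (2.48), Ugt2b34 (5.39), Grid1 (5.16) and 1700066C05Rik (5.12) were above the sum. Ugt2b34 and 1700066C05Rik were among the lowest genes on the alpha arrays, where dim probes were low as well, and their signals are not given here. In the 12-array fit 0 genes passed (1160 at an unadjusted p under 0.05), Acacb turned to 0.16, and smaller by over 1.5 times were Ndufv1 (-1.40), Ndufa9 (-0.73), Cyc1 (-1.51), Atp5g1 (-1.76), Atp5d (-1.84), Got1 (-1.90), Idh3a (-1.68), Echs1 (-1.17), Slc25a20 (-0.97), Mrpl2 (-0.42), Bnip3 (-1.52), Bhlhe40 (-0.75), Lpin1 (-1.25), Hba-a2 (-1.49), Zfp445 (-0.94), Kdm6b (-2.19) and Grid1 (1.64).

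Other splits of the arrays were counted beside these results. In the 11-array fit 2 of 100 splits of the 8 arrays against floxed RNA gave as many non-additive genes, the real one with 401 included, and the highest other split gave 590. The share of 2 in 100 is under 5%, but it does not exclude chance. The fit was chosen after the data were seen, and the splits took no account of replicate numbers. A grouping other than the real one gave more genes. The count was 0 with beta 3 kept and without alpha 3, beta 1 or beta 2, so it is not shown to come from the groups. In the 12-array fit the real count was 0, which all 100 splits reach by construction, so these splits say nothing for the groups, and the highest other gave 1148. For double against beta in that fit the real count was 0 in 10 splits, the highest other was 219, and all 10 reached it; so few splits cannot give a share under 0.05. With the sign of 1 array turned, 1 of 4 patterns, the real one, gave as many genes on the alpha (1499, highest other 1), double (194, highest other 3) and direct arrays (1418, highest other 0), and 4 patterns are too few for a share under 0.05.

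Respiratory chain and citric acid cycle genes, 91 in 5 lists, had a median of -0.92 on the double arrays, with 89 below 0. A brightness trend of the arrays would lower random lists of equal dimness alike, yet 0 of 10000 had so low a median, a share of at most 0.01%, the smallest these lists can give. The trend also ran opposite ways on double 1 and double 3 (1.54 and -2.44 for bright minus dim probes), where the median was -0.68 and -1.20. Brightness within a class of dimness was not measured, and random lists lack the correlation among the pooled genes, estimated at 0.25. A part of the trend therefore stays open. Dye bias cancels in double minus alpha, and the control RNA too if the arrays held the same, which the labels do not say. The median there stayed at -0.97 with 85 of 91 genes lower (camera p = 0.00917 with an estimated correlation). This argues against the dye, and against a control RNA common to the arrays, as the whole cause. With dim signals kept and arrays centred it was -0.99 over 106 genes, from the same alpha and double arrays, so this is no separate test. In double minus beta the median was -0.90 without beta 3, but -0.14 with beta 3 kept and nothing else changed, so that difference rests on leaving out 1 array. Loss of both coactivators may lower these genes, and on the direct arrays, which hold no floxed RNA, the median was -0.54 with 61 of 91 lower, but camera gave p = 0.397 with an estimated correlation, so this stays open. With no dye exchange and 2 beta arrays, a mixture of these sources cannot be told apart from it.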

How the results depend on the processing

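The 11-array fit and every alternative to it, array weights and leaving out the third beta array were chosen after the data were seen. Counts follow the order alpha, beta, double, direct, double against beta and non-additive, and those named are the ones that moved by over 1.5 times. The cause of the moves was not tested, except that fewer arrays or genes enter some fits by construction. What limits the precision is the number of arrays and of usable values. Between 47.8% and 74.2% of probes were usable, by a rule that reads the ratio and not the signal.

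The 12-array fit called 4, 0, 0, 0, 0 and 0 genes. Centring gave 17 on the alpha and 4 on the direct arrays, and scaling 551 on the alpha, 34 on the double and 245 on the direct arrays. Probe level gave 0 on the alpha and 3 on the double arrays, and complete genes 11 on the alpha and 2 on the double arrays. Channel labels gave 4 on the double, 2 on the direct arrays and 4 non-additive. A fixed block gave 53 on the alpha, 5 on the double and 469 on the direct arrays. The dye term gave 0 on the alpha arrays. With the arrays of the comparison alone there were 0 on the alpha and 319 on the direct arrays. Leaving out each replicate number gave 0 to 3 on the alpha, 0 to 9 on the double and 0 to 1 on the direct arrays.

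Without the third beta array there were 88 on the alpha, 17 on the double, 736 on the direct arrays and 48 non-additive, and with centring too 1290, 72, 1055, 204 and 1 for double against beta. The 11-array fit gave 1499, 1, 194, 1418, 1 and 401. Array weights gave 4893, 1022, 132, 1246, 27 and 1959. The alternatives named before the data were examined otherwise left the counts of beta, double against beta and the non-additive response at 0, except the 4 by channel labels given above.

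Keeping beta 3 in the 11-array fit, with nothing else changed, gave 84 on the alpha, 0 on the beta, 17 on the double and 172 on the direct arrays, and 0 for double against beta and non-additive. In the 11-array fit, keeping dim signals gave 0 on the beta, 72 on the double arrays and 204 non-additive. Without centring there were 123 on the alpha, 0 on the beta, 34 on the double arrays, 0 for double against beta and 0 non-additive. Centring within dimness classes gave 0 for double against beta. The dye term gave 409 on the alpha, 0 on the beta, 1 on the double, 8 on the direct arrays and 1521 non-additive. By construction the last 2 are the tests of double minus alpha and of direct minus beta. A fixed block gave 0 on the beta arrays, and a random block 2 for double against beta. The numbers were not taken to pair all arrays. With group means removed ratios correlated above 0.1 in only 9 of 15 pairs of the same number (11 of 18 with all 12 arrays), and not every array correlated best with its own number. Without beta 3, though, every same-number pair among the alpha, beta and double arrays was at 0.11 to 0.48. Each same-number pair below 0.1 held a direct array. Alpha knockout RNA is the denominator there, so a shared alpha RNA would lower the correlation of an alpha with a direct array. These pairs were at -0.062, -0.346 and -0.041 for numbers 1 to 3. The limit of 0.1 cannot judge them. The mean was 0.14 for the same and -0.07 for other numbers, and alpha 1, beta 1 and double 1 correlated at 0.43 to 0.47. A shared day or RNA therefore stays open for arrays of the same number against floxed RNA. The block moved no other count by over 1.5 times, and blocked contrasts of several groups are approximate where values are missing. Channel labels gave 2 on the beta, 0 on the double, 761 on the direct arrays, 0 for double against beta and 0 non-additive, and 1922 on the alpha arrays. Complete genes gave 3 for double against beta. With the arrays of the comparison alone there were 660 on the alpha, and 0 on the beta, double and direct arrays and for double against beta. Leaving out each array gave 66 to 1788 on the alpha, 0 to 3 on the beta, 49 to 224 on the double, 310 to 1507 on the direct arrays, 0 to 2 for double against beta and 0 to 888 non-additive. Where this left 1 beta array, it was assumed to vary like the other groups.

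Lists called by camera in the 12-array fit numbered 7, 5, 8, 7, 2 and 2, and 0 in each comparison with an estimated correlation or with fry. Directions differed between the fits, with 0 up and 5 down on the beta arrays and 2 up and 0 down for double against beta, against 2 up and 1 down and 0 up and 12 down in the 11-array fit, and with 6 up and 1 down on the alpha arrays against 1 and 1. Centring gave 4 lists on the direct arrays and 0 non-additive, and channel labels 8 on the beta arrays, 11 for double against beta and 9 non-additive. Leaving out each replicate number gave 4 to 8 on the alpha, 3 to 9 on the beta, 2 to 7 on the direct arrays, 3 to 8 for double against beta and 0 to 11 non-additive. The 11-array fit gave 2, 3, 9, 2, 12 and 9 lists. In it an estimated correlation gave 0 on the alpha, beta and direct arrays, 4 for double against beta and 2 non-additive. Fry, which asks only whether a list moves one way, gave 13 on the alpha, 11 on the direct arrays and 6 for double against beta. Keeping beta 3 gave 5 on the beta arrays, all down, 1 on the direct arrays, 2 for double against beta, both up, and 0 non-additive. Dimness classes gave 5 non-additive. Channel labels gave 10 on the beta, 0 on the direct arrays, 1 for double against beta and 2 non-additive. Leaving out each array gave 1 to 2 lists on the alpha, 1 to 3 on the beta and 0 to 5 on the direct arrays, and 8 to 10 on the double arrays, where every alternative of the 11-array fit gave 7 to 11.

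Over 198 pairs of a gene and a comparison, a part of those chosen by the rule, 4534 values were recomputed. Of these 3051 kept their direction and their side of the threshold, 1458 kept their direction and lost the threshold, 3 gained it and 22 reversed. Efcab3 on the direct arrays turned to -0.36 with the dye term, and the non-additive Acacb to 0.16 in the 12-array fit. The other 20 passed the threshold neither before nor after the turn. Among the rule's genes outside the 198 pairs, the non-additive Dstn turned from -3.93 to 0.44 in the 12-array fit. On the beta arrays Ankrd2 turned to -0.0745 and Tnnt1 to -0.129 in the 12-array fit. For double against beta Acadvl turned to 0.31, Bhlhe40 to 0.46, Hba-a2 to 0.10, Mrpl12 to 0.0334, Ppargc1b to 0.20, Tfb1m to 0.15 and Tfb2m to 0.88 in the 12-array fit, and Acadvl to 0.0854, Bhlhe40 to 0.24 and Tfb2m to 0.65 with its arrays centred, and Bhlhe40 to 0.14 and Tfb2m to 0.38 in the 11-array fit with beta 3 kept. By channel labels Atp5g1 turned to 0.14, Cox5b to 0.0515, Ppargc1a to 0.44, Slc25a3 to 0.38 and Tfb2m to 0.0697. The non-additive Ppargc1a was -0.14 to 0.89 with each array left out, the lowest without alpha 2. Of the 157 called values among the 198 pairs, 32 were smaller by over 1.5 times in the 12-array fit. These were 4 of 39 on the double, 9 of 41 on the direct arrays, 18 of 34 non-additive and Chchd10 for double against beta. The rule's other genes were not counted. In the label check the match with the authors' means was 100% by titles and 1.37% by channel labels for the double group of the down table.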

Other observations

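Genes and tests named here were all chosen after their values were seen. Fndc5, on chromosome 4 (129136870 to 129144593), the precursor of the secreted peptide irisin, had a log2 ratio of -2.43 ± 0.59 (SD, n = 3; adjusted p = 0.00111) on the double arrays, -0.85 ± 0.24 (SD, n = 3; adjusted p = 0.0408) on the alpha arrays and -1.07 ± 0.17 (SD, n = 3; adjusted p = 0.0184) on the direct arrays. On the beta arrays it was 0.26 ± 0.22 (SD, n = 2; adjusted p = 0.706), but -1.70 on beta 3, and -0.40 with it kept. Nnt, the mitochondrial transhydrogenase, was at 1.56 ± 0.34 on the alpha (SD, n = 3, adjusted p = 0.00467) and 1.19 ± 0.39 on the double arrays (SD, n = 3, adjusted p = 0.0322), above 0 on all 6. Its value was 0.62 ± 0.37 (SD, n = 2) on beta 1 and beta 2, but -2.61 on beta 3, and -0.46 on the beta arrays with beta 3 kept. On the direct arrays Nnt was at -0.57 ± 0.24 (SD, n = 3, adjusted p = 0.124 in limma). The mice were of a mixed background, and the strain alleles that each group carried at Nnt are not given here. A strain difference was therefore not tested. Pprc1, the related coactivator, was at 1.19 ± 0.41 (SD, n = 3; adjusted p = 0.0554) on the alpha arrays.

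Of 66 genes of cytosolic ribosomal proteins, 31 rose and 0 fell on the direct arrays, with a median of 0.69 and 54 above 0. On the double arrays 3 rose and 0 fell, with a median of 0.43, and on the alpha arrays 10 rose and 6 fell, with a median of 0.25. On the beta arrays 0 passed limma's threshold, and the median was 0.33. Myh4, the fast myosin that dominates this muscle, could not be fitted, since its 2 probes lay on the array factor, where signals are equal, on 5 and 3 of the 12 arrays.

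The 1050 genes called higher on the alpha arrays had a median of 1.22 there, 0.85 on the beta, 0.37 on the double and -0.83 on the direct arrays. A common dye bias would raise them on the direct arrays as well, where the highest of the 3 array medians was -0.54. Floxed control RNA alone would leave the direct arrays near 0, where the group median was -0.83. Alpha knockout RNA alone would leave the beta arrays near 0; the medians were 0.91 and 0.74 on beta 1 and beta 2 but -0.98 on beta 3, where genes called lower on the alpha arrays were at -0.96 too, so this source stays open. A trend with brightness runs opposite ways on the alpha and direct arrays, and over the 11 arrays it went with these medians at a Spearman rho of 0.864. Centred within classes of dimness, the genes still had medians of -0.80 to -0.52 on the direct and of 0.71 and 0.77 on the beta arrays, which argues against the measured trend as the whole cause; brightness within a class was not measured, so a part stays open. Neither a common dye bias nor the control RNA alone gives the pattern; a mixture may, and the share that the floxed reference common to 3 groups adds could not be simulated, since the spread of the control was not measured.

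Titles and channel labels name different RNA on 6 arrays, and Ppargc1a was used to weigh whether the channel labels name the RNA. Grouped by titles, the 6 alpha and double arrays minus the 3 beta arrays gave -0.92 (one-sided exact permutation p = 0.0238 over 84 splits). Grouped by channel labels the same difference was 0.87, in the direction opposite to the labels, with an exact permutation p of 0.0833 for that direction, which does not decide. Correlations were also taken over the log2 ratios that the rule for dim or equal signals kept. They averaged 0.28 in the 9 pairs of arrays with the same title, 0.38 in the 9 pairs with the same channel label and 0.19 in the other 18. Medians of the pooled respiratory chain and citric acid cycle genes were -0.68, -0.77 and -1.20 on double 1 to 3. They were -0.28 to 0.19 on the alpha arrays and 0.11 and -0.22 on beta 1 and beta 2, which follows the titles on these arrays. With beta 3 kept, which its channel label names a double knockout, the beta median was -0.80. Arrays with the same channel label also share their replicate number, so a shared day and a shared RNA cannot be told apart, and the labels stay open although the authors' means follow the titles.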
